A study of Arabidopsis thaliana with 6 samples.

How the data were processed

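Inflorescences of 4-week-old Arabidopsis thaliana plants of the Col-0 ecotype were compared between 3 wild-type samples and 3 samples of an rdr2 mutant, on custom Agilent arrays carrying probes for long intergenic noncoding RNAs (lincRNAs). Per the labels, each sample is a biological replicate of pooled open flowers, buds and some young siliques, and 0.5 µg of DNase-treated total RNA was labelled with Cy3. The sample titles name an rdr2 mutant without an allele, and the protocols name a single allele. A genotype field numbers the allele differently in each of the 3 mutant samples. The samples were treated as 1 group, as titled.

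Each array was scanned by the authors in a single channel and extracted with Agilent Feature Extraction 10.5.1.1 (5 arrays) or 10.7.3.1 (mutant replicate 3). Per the file headers and columns, the processed signal is an intensity after background subtraction and spatial detrending within the array, and the median spot and background signals are raw intensity values. The deposited value table holds log2 values. Recomputing them showed that they are log2 processed signals floored at 1 and quantile normalized between arrays, with at least 99.86% of values on each array within 0.1.

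Each array held 15013 probes besides 536 control spots, each probe on 1 spot, under 5154 transcript names. Names of transcription units formed the lincRNA class (13245 probes). Locus names were looked up in a RefSeq gene table of assembly TAIR10.1, where 400 of 405 loci were found, and gave the classes annotated noncoding RNA (1108 probes), protein-coding (285), miRNA precursor (339, with names that state a miRNA) and other (36). That transcription unit names denote lincRNAs was taken from the names and the title. A start coordinate stands in the probe annotation for 930 transcription units and not for the other 3569; the build of these coordinates is not given in the sources used here. Unit numbers followed the known starts in order on every chromosome, so units without a start were placed between the nearest known starts.

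The main values were log2 processed signals minus the log2 of each array's 75th percentile over the 2369 probes well above background on all 6 arrays. In the text, scaled signal is the same ratio with the percentile set to 100. Spots marked as uneven were kept, since no probe had a second spot; they numbered 1 to 5 per array among tested probes. The 3345 probes well above background on all 3 arrays of at least 1 group were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the sole term), with Benjamini-Hochberg adjustment over these probes and a threshold of adjusted p 0.05. Figures were drawn with matplotlib 3.10.9. Simulated data had 200 changed probes in each of 20 runs and noise drawn independently for each array. There this procedure recovered 75.8% of 4-fold and 46.2% of 2-fold changes, and 6.02% of its calls were false. These shares do not cover noise shared by the arrays of a slide. In 100 runs with such noise (within-slide correlation 0.773) and no changed probe, the median number of calls was 1 and the highest 17. The shared noise was drawn separately for each probe, so these runs do not cover a slide effect that moves many probes together.

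Where a probe was not well above background on any array of a group, its fold is given as a bound, computed against a floor: on each array of the dim group, the higher of the lowest well-above-background signal and the probe's own signal. The named transcripts were set by a rule fixed before the data were examined: the 12 largest changes in each direction past the threshold with no overlap between the groups' arrays, 1 probe per name, together with RDR2 and the members of fixed gene lists past the threshold, at most 4 per list, or the 2 with the smallest p. Other transcripts named were chosen after their values were seen.

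The fixed lists were RNA-directed DNA methylation machinery, DNA methylation maintenance and demethylation, other small-RNA pathway genes, known RdDM-silenced genes, named noncoding RNA genes, floral organ identity, tapetum and anther markers, mature pollen markers, carpel, ovule and seed markers, leaf and photosynthesis markers, root markers, stress response and housekeeping genes. Lists with at least 3 tested genes were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry. Both took probes as the members of a list, several per gene, so the preset correlation counts probes of 1 gene as nearly independent. The estimated correlation was 0.16 for RNA-directed DNA methylation and 0.41 for the other small-RNA genes. Camera values at the preset correlation therefore overstate the evidence. Lists of jasmonate, clock, light, abscisic acid and cold, and seed maturation genes, and of miR156 and miR157 precursors, were formed after the data were examined. Shares of calls were compared by two-sided Fisher's exact tests. Transcription units within 3 Mb of a point set as the centre of each chromosome were called pericentromeric.

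Slides and scan sessions, read from the file headers, were nested in the groups: wild-type replicates 1 and 2 shared a slide, mutant replicates 1 and 2 shared another, and each replicate 3 had a slide of its own. Slide therefore could enter only as a random block (within-slide correlation 0.773). Alternatives covered the scaling, the background correction, the source of values, the filter, the variance model, the threshold, averaging the probes of a name, a replicate block, the slide block, leaving out each array, the width of the pericentromere and the use of interpolated positions. The scan date forms the same blocks as the slide and was not run apart from it. Background correction by normexp (offset 50) used median spot signals. Overlap with transposable elements and a comparison of both strands of a locus were not analysed here, for want of an element annotation and of paired-strand probes above background. The number of arrays, 3 per group, limits the precision of every value.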

Results

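The arrays measured RNA from inflorescences of 3 wild-type samples and 3 samples of a mutant in RDR2 (RNA-DEPENDENT RNA POLYMERASE 2), the enzyme that turns RNA polymerase IV transcripts into the double-stranded precursors of small interfering RNAs that guide DNA methylation. The question, from the series title, was which lincRNAs RDR2 regulates. Of 15013 probes per array, 37.9%, 37.4% and 24.1% were well above background in wild-type replicates 1 to 3, and 17.56%, 17.8% and 24.8% in mutant replicates 1 to 3. The 75th percentile intensity used for scaling was 367, 305 and 371 in the wild type and 162, 155 and 285 in the mutant, so the mutant arrays were the dimmer ones. Across 2369 probes, which are not independent replicates, arrays of a shared slide correlated at r of 0.995 in the wild type and 0.994 in the mutant. Other arrays of the same group correlated at 0.970 to 0.977, and arrays of different groups at 0.947 to 0.957.

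RDR2 itself (AT4G11130, chromosome 4) fell in the mutant on each of its 3 probes, with log2 fold changes of -2.73, -2.69 and -2.63. At the probe log2 fold change of -2.69 (SE 0.125), the scaled signal was 410 ± 39.0 in the wild type and 63.3 ± 2.73 in the mutant (SD, n = 3 each), 6.47-fold lower, with a limma adjusted p of 0.000168. All 3 mutant arrays lay below all 3 wild-type arrays. The RDR2 signal stayed well above background on the mutant arrays; where the probes lie relative to the mutation is not given in the sources used here. The fall passed the threshold under each of the 25 alternatives run for it, with adjusted p of at most 0.0305.

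LincRNAs rose and fell in the mutant, and some of the largest rises started from background in the wild type. Folds and bounds are those of 1 probe per unit, the probe with the smallest p. AT1TU053480 (chromosome 1, between units starting at 16249256 and 16420072) was at least 26.5-fold higher, with a log2 fold change of 6.64 (SE 0.142, adjusted p = 3.33e-05), and rose on 3 of 3 probes. AT2TU018110 (chromosome 2, between 5720867 and 6082686) was at least 77.4-fold higher (a second probe was above background on 2 wild-type arrays) and AT2TU059860 (chromosome 2, between 16980435 and 17504550) at least 25.5-fold higher. AT2TU000580, near one end of chromosome 2 (between 97610 and 193293), was well expressed in both groups and rose 32.0-fold, from a scaled signal of 213 ± 11.8 to 6832 ± 304 (SD, n = 3 each). AT5TU022670 (chromosome 5, between 6158888 and 6592762) rose 23.4-fold, from 78.7 ± 3.97 to 1843 ± 180. It was called on both tested probes, and its remaining probe was well above background on no array of either group. Its neighbour AT5TU022680 was at least 7.39-fold higher. AT5TU022680 was called on 2 of 3 probes; the other, above background on 2 wild-type arrays, stood at 2.14 on the log2 scale (adjusted p = 0.136), with overlapping groups. The other rises among the named units were AT4TU016190 (23.0-fold, chromosome 4, called on 2 of 3 probes, the other at 2.00 on the log2 scale with adjusted p = 0.119), AT1TU048310 (16.4-fold, chromosome 1, start 13872213) and AT3TU040020 (at least 8.31-fold, chromosome 3, start 11480457).

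In the opposite direction, AT4TU019690 (chromosome 4, between 5738570 and 5985499) had a scaled signal of 185 ± 11.6 (SD, n = 3) in the wild type on a probe above background on no mutant array, a fall of at least 89.1-fold (log2 fold change -8.02, SE 0.343, adjusted p = 0.000119). It fell on 3 of 3 probes, 1 of which was above background on 1 mutant array. AT4TU019690 lies on the same chromosome as RDR2, and linkage to the mutation was not tested. Its neighbour AT4TU019700 was at least 2.76-fold lower and fell on both tested probes; the remaining probe, too dim to test, differed by -0.19. AT1TU058220 (chromosome 1, between 17684411 and 18290218) fell 6.07-fold, from 36.8 ± 2.68 to 6.05 ± 0.429. Other falls on probes above background in the wild type and on no mutant array were those of AT5TU047760 (at least 6.64-fold lower, called on 2 of 3 probes, the other being above background on 1 mutant array), AT5TU014740 (at least 3.92-fold, chromosome 5, start 4202199), AT3TU036030 (at least 2.95-fold, chromosome 3, start 10303885), AT1TU062080 (at least 2.71-fold) and AT2TU038730 (at least 2.59-fold); the last 4 of these were tested on 1 probe each. AT1TU045300, above background on 1 mutant array, had a log2 fold change of -2.64.

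The sizes of these changes depended on the processing, and the bounds hold for the main values only. With normexp, whose offset of 50 draws dim signals together, the log2 fold changes of the rises were 1.52 for AT1TU053480, 2.50 for AT2TU018110, 1.39 for AT2TU059860, 2.34 for AT4TU016190, 1.81 for AT1TU048310, 0.65 for AT3TU040020 and 0.48 for AT5TU022680. Those of the falls were -3.10 for AT4TU019690, -0.59 for AT5TU047760, -0.34 for AT5TU014740, -0.26 for AT4TU019700, -0.27 for AT3TU036030, -0.18 for AT1TU062080, -0.30 for AT1TU045300, -0.92 for AT1TU058220 and -0.21 for AT2TU038730. The bright units AT2TU000580 (5.01) and AT5TU022670 (4.27) changed little. Averaged over the probes of a name, AT1TU053480 stood at 5.83, AT2TU059860 at 5.35, AT4TU016190 at 3.45, AT5TU022680 at 2.99, AT4TU019690 at -6.67 and AT5TU047760 at -3.68.

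Several of these calls rested on the processing or on single arrays. With slide as a random block, adjusted p was 0.0625 for AT5TU022680, 0.0635 for AT3TU036030, 0.0779 for AT1TU062080, 0.0980 for AT1TU045300 and 0.155 for AT2TU038730, which ended those calls. The calls of AT3TU036030, AT1TU062080 and AT2TU038730 were also lost without wild-type replicate 1 (adjusted p = 0.0799, 0.0612 and 0.0571), wild-type replicate 2 (0.0854, 0.0655 and 0.0643) or mutant replicate 2 (0.0775, 0.0594 and 0.0561). That of AT3TU036030 was lost as well without mutant replicate 1 (0.0799). Quantile normalization and the deposited table ended the calls of AT1TU045300 (adjusted p = 0.0694 and 0.0696) and AT2TU038730 (0.0661 and 0.0649). Normexp ended those of AT4TU019700 (0.0528), AT1TU062080 (0.154) and AT2TU038730 (0.0785), and the unmoderated test that of AT3TU036030 (0.0604). AT3TU036030, AT1TU062080, AT1TU045300 and AT2TU038730 were also not called with no filter (0.134, 0.101, 0.0910 and 0.105) or with the filter on at least 1 array (0.0993, 0.0679, 0.0548 and 0.0669). A threshold of 0.01 left out AT3TU036030, AT1TU062080 and AT2TU038730. With the arrays of a shared slide averaged, 7 of these lincRNAs missed the threshold: AT4TU016190 (0.0568), AT5TU022680 (0.0568), AT4TU019700 (0.0553), AT3TU036030 (0.249), AT1TU062080 (0.152), AT1TU045300 (0.1265) and AT2TU038730 (0.103). Without the 2 dimmest arrays 4 did: AT4TU016190 (0.0883), AT5TU022680 (0.115), AT3TU036030 (0.194) and AT1TU045300 (0.0530).

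Among all lincRNA probes, 1968 of 13245 (14.9%) were bright enough to test, covering 1327 transcripts. Of these transcripts, 78 rose and 121 fell, each counted by its probe with the smallest p. By probe, 114 rose and 153 fell, and adjusted over the list alone the counts were 114 and 153. A change of at least 2-fold was seen in 69 rising and 107 falling probes. Transcripts AT1TU045280, AT2TU034460 and AT3TU071530 had probes called in opposite directions. The number of falls depended on the processing, being 68 with quantile normalization, 27 with the 75th percentile over all probes, 67 with normexp and 68 in the deposited table. Slide as a random block gave 33 higher and 29 lower. Leaving out wild-type replicate 1 gave 58 and 44, wild-type replicate 2 49 and 38, mutant replicate 1 51 and 59, and mutant replicate 2 50 and 51. There were 591 falls without wild-type replicate 3 and 201 rises without mutant replicate 3.

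Over all classes, 109 of 1862 transcripts rose and 199 fell, each counted by its probe with the smallest p. By probe, 171 of 3345 rose and 284 fell, and 37.6% of these calls were rises. At an unadjusted p under 0.05 the counts were 324 and 786, and 102 and 161 called probes changed at least 2-fold. Of 225 called transcripts with several tested probes, 60 had every tested probe called in 1 direction. The median tested probe lay at -0.26 on the log2 scale, and the balance between rises and falls followed the scaling: 172 and 146 with quantile normalization (54.1% rises, median -0.02), 183 and 143 with median scaling (56.1%), 125 and 36 with the 75th percentile over all probes (77.6%, median 0.35). They were 227 and 242 with normexp (48.4%), and 171 and 138 in the deposited table (55.3%). With slide as a random block 57 and 55 probes passed, all 112 of them among the calls above. Each left-out array moved a count by over 1.5 times: 89 and 83 without wild-type replicate 1, 77 and 75 without wild-type replicate 2, and 186 and 770 without wild-type replicate 3. The counts were 79 and 101 without mutant replicate 1, 80 and 95 without mutant replicate 2, and 277 and 446 without mutant replicate 3.

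**Figure D1:**
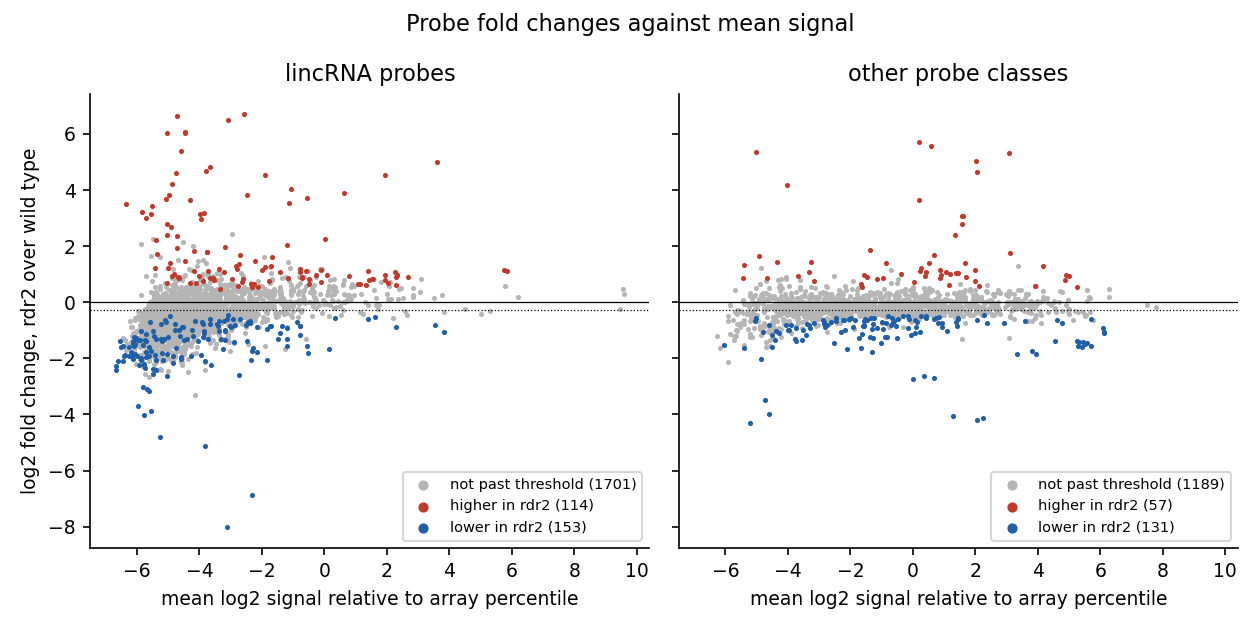
Log2 fold change of the rdr2 mutant against wild type (vertical axis) by mean log2 signal relative to the array's percentile (horizontal axis) for the 3345 tested probes, with lincRNA probes and other classes in separate panels; red points are higher and blue points lower past adjusted p 0.05, grey points are not called, and the dotted line is the median of all tested probes. The lincRNA panel holds 114 rises and 153 falls, the other panel 57 and 131, and the median line lies at -0.26.

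**Figure D2:**
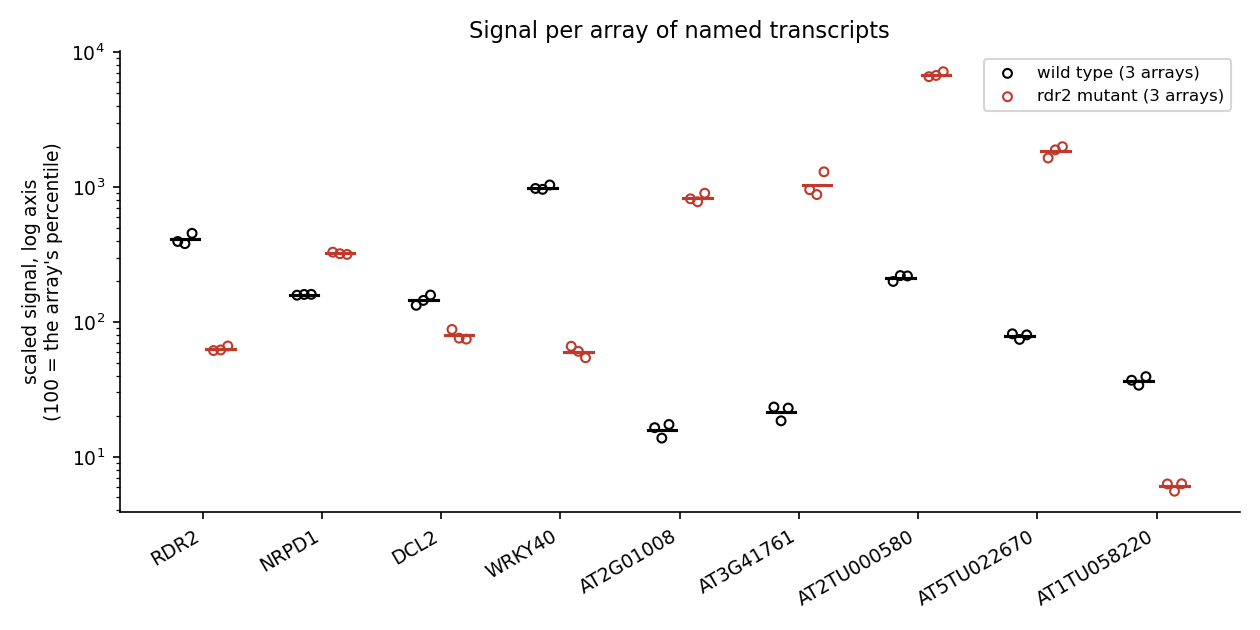
Scaled signal on a log axis (100 is the array's 75th percentile) of 9 transcripts on each of the 3 wild-type and 3 mutant arrays; points are arrays and bars are group means. For each transcript the 3 arrays of 1 group lie on one side of the 3 of the other, as for RDR2 at 410 against 63.3 and WRKY40 at 993 against 60.3.

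The largest rises outside the lincRNA class were those of AT2G01008 and AT3G41761, a pair of loci close to ribosomal RNA genes. AT2G01008, on chromosome 2 and annotated as protein-coding, rose 52.7-fold, from a scaled signal of 15.9 ± 1.87 to 833 ± 62.4 (SD, n = 3 each), on 3 of 3 probes (log2 fold change 5.72, SE 0.143, adjusted p = 3.70e-05). AT3G41761, a noncoding RNA on chromosome 3, rose 47.9-fold, from 21.6 ± 2.72 to 1045 ± 223, on 2 of 2 probes. In the TAIR10.1 gene order the nearest ribosomal RNA genes are 2 genes from AT2G01008 and 3 from AT3G41761. The long noncoding RNA AT4G34071 was at least 13.6-fold higher on its best probe and was called on 2 of 3 probes, the lowest being -0.18 on the log2 scale. WRKY40 (AT1G80840), a transcription factor of pathogen and wound responses, fell 16.5-fold, from 993 ± 39.6 to 60.3 ± 5.88, on 3 of 3 probes (log2 fold change -4.04, SE 0.127, adjusted p = 4.43e-05), and the noncoding RNA AT2G06002 was at least 5.70-fold lower. With normexp the log2 fold changes were 4.58 for AT2G01008, 4.47 for AT3G41761, 0.77 for AT4G34071, -3.32 for WRKY40 and -0.45 for AT2G06002, and AT4G34071 stood at 3.11 over its probes.

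In the smaller classes fewer transcripts rose than fell. Of 89 protein-coding transcripts tested, 5 rose, which were, chosen after their values were seen, AT2G01008, the auxin-responsive SAUR-type gene AT5G20820 (log2 fold change 1.07), NRPD1 (1.02), the cold-inducible KIN1 (0.85, on 1 of 2 probes) and MEE26 (0.63). Another 16 fell. Of 93 miRNA precursors, 3 rose (MIR825 at 1.31, MIR775 at 0.88 and MIR402 at 0.85 on the log2 scale). Another 8 fell, from MIR860 at -0.75 to MIR157a at -2.01, the latter well above background on 1 mutant array. The 3 called transcripts in the class of other RNAs were isoforms of AT1G24825, at -1.10, -1.38 and -1.40. MEE26, MIR825 and MIR402 lost their calls with quantile normalization (adjusted p = 0.0550, 0.0708 and 0.0857) and in the deposited table (0.0615, 0.0702 and 0.0847). MIR825 and MIR402 also lost them with normexp (0.144 and 0.229), and MEE26 with median scaling (0.0653). Of the 16 falling protein-coding transcripts, 11 were called with quantile normalization, 4 with median scaling, 2 with the 75th percentile over all probes, 13 with normexp and 9 in the deposited table. Of the 8 falling miRNA precursors these counts were 5, 2, 0, 4 and 5. With the 75th percentile over all probes, 2 of the 5 rising protein-coding transcripts (AT2G01008 and AT5G20820), 1 of the 3 rising precursors (MIR825) and 0 of the 3 AT1G24825 isoforms kept their calls. Of 344 annotated noncoding RNAs, 23 rose and 51 fell. By probes, rises and falls numbered 40 and 83 for annotated noncoding RNAs, 12 and 30 for protein-coding genes, 5 and 10 for miRNA precursors and 0 and 8 for other RNAs. Adjusted over the list alone they were 40 and 81, 12 and 32, 5 and 7, and 0 and 9. The sums of 57 rises and 131 falls were 57 and 78 with quantile normalization, 57 and 40 with median scaling, and 33 and 9 with the 75th percentile over all probes. They were 58 and 70 in the deposited table and 24 and 26 with slide as a random block. They were 31 and 39 without wild-type replicate 1, 28 and 37 without wild-type replicate 2, 28 and 42 without mutant replicate 1 and 30 and 44 without mutant replicate 2. There were 224 falls without mutant replicate 3.

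Whether lincRNAs fell as often as other classes depended on the unit counted. By probe, 7.77% of lincRNA, 8.72% of annotated noncoding RNA and 11.95% of protein-coding probes fell (Fisher's exact adjusted p = 0.578 and 0.169 against lincRNA). By transcript the shares were 9.12%, 14.8% (odds ratio 0.576, adjusted p = 0.0164) and 17.98% (odds ratio 0.458, adjusted p = 0.0423). A transcript counted as fallen when its probe with the smallest p was called lower. This favours classes with more tested probes per transcript: 1968 probes of 1327 lincRNAs, 952 of 344 annotated noncoding RNAs and 251 of 89 protein-coding transcripts. The difference by transcript is therefore not read as a difference between classes. Of miRNA precursors 8.60% fell by transcript (odds ratio 1.07, adjusted p = 1). Median log2 fold changes of the tested probes were -0.36 for lincRNA, -0.16 for annotated noncoding RNA, -0.22 for protein-coding and -0.21 for miRNA precursors. No difference in the share of rises passed, the smallest adjusted p being 0.232 by probe.

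Of the genes of RNA-directed DNA methylation on the array, 1 passed the threshold. NRPD1 (AT1G63020, chromosome 1), the largest subunit of RNA polymerase IV, which acts upstream of RDR2, rose 2.02-fold on 3 of 3 probes, from a scaled signal of 159 ± 1.22 to 322 ± 6.30 (SD, n = 3 each; log2 fold change 1.02, SE 0.104, adjusted p = 0.00414; 1.28 relative to the median probe). NRPE1, the largest subunit of RNA polymerase V, had a log2 fold change of -0.32 (SE 0.127, adjusted p = 0.142) on its best probe and 0.14 over its probes. DCL3, the Dicer of this pathway, stood at -0.38 (SE 0.127, adjusted p = 0.105). Of 19 listed genes these 3 were on the array, 1 rose and none fell, and adjusted over the list alone the counts were the same. The mean was 0.27 and the median 0.05, with camera adjusted p = 0.0892, adjusted p = 0.484 with an estimated correlation, and fry adjusted p = 0.0178 for a change on balance in 1 direction. The camera call was gained with the filter on at least 1 array (adjusted p = 0.0179). The NRPD1 call was lost with the 75th percentile over all probes (adjusted p = 0.0599), with no filter (0.223), with the filter on at least 1 array (0.0811), with the arrays of a shared slide averaged (0.163) and without the 2 dimmest arrays (0.0869).

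Among other small-RNA genes, DCL2 (AT3G03300, chromosome 3), a Dicer that makes small RNAs from viral and transgene RNA, fell 1.83-fold on 3 of 3 probes, from 145 ± 12.8 to 79.5 ± 7.41 (SD, n = 3 each; log2 fold change -0.87, SE 0.136, adjusted p = 0.0143; -0.61 relative to the median probe). DCL1, DCL4 and AGO2 did not pass, with log2 fold changes of -0.34, -0.05 and -0.25. Of 16 listed genes 4 were on the array; 1 fell and none rose, and adjusted over the list alone the counts were the same. The list's mean was -0.34, and 0.28 with the 75th percentile over all probes. On the main values camera gave adjusted p = 0.188 (adjusted p = 0.585 with an estimated correlation) and fry adjusted p = 0.0349. Fry tests against 0, while the median tested probe lay at -0.26. Relative to that probe, DCL1, AGO2 and DCL4 stood at -0.001, 0.094 and 0.26 over their probes, and DCL2 at -0.66. On the main values fry therefore cannot separate a fall of the list from the shift of the median probe. That shift was -0.66 among the dimmest 1115 tested probes and -0.08 among the brightest 1115, so the median probe is not a fixed reference. With quantile normalization (median probe -0.02), DCL1, AGO2, DCL4 and DCL2 stood at -0.38, -0.26, -0.02 and -0.97 over their probes. There camera at the preset correlation gave adjusted p = 0.00641. Whether the list fell was not decided. The DCL2 call was lost with median scaling (adjusted p = 0.159), the 75th percentile over all probes (0.837), no filter (0.223), the filter on at least 1 array (0.156) and slide as a random block (0.112). It was also lost with the arrays of a shared slide averaged (0.2115), without the 2 dimmest arrays (0.122), and without wild-type replicate 1 (0.0512), wild-type replicate 2 (0.0767) or mutant replicate 2 (0.0681). A 2-fold minimum and a threshold of 0.01 left it out as well.

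Of the 11 stress response genes, the cold- and drought-inducible COR15A and RD29A were on the array and neither passed in limma, with 1 at an unadjusted p under 0.05. COR15A had a log2 fold change of 0.46 (adjusted p = 0.141) and RD29A -0.22 (adjusted p = 0.271), and RD29A lay above 0 with each of the other scalings. COR15A passed without wild-type replicate 3 (adjusted p = 0.0344) and with array weights (0.00409), and RD29A with array weights (0.0193). The other 10 fixed lists, which cover DNA methylation maintenance, RdDM-silenced genes, named noncoding RNAs, floral organ identity, tapetum, pollen, carpel and seed, leaf, root and housekeeping genes, had 0 members under their locus names on the array, so tissue make-up could not be compared with them.

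**Figure D3:**
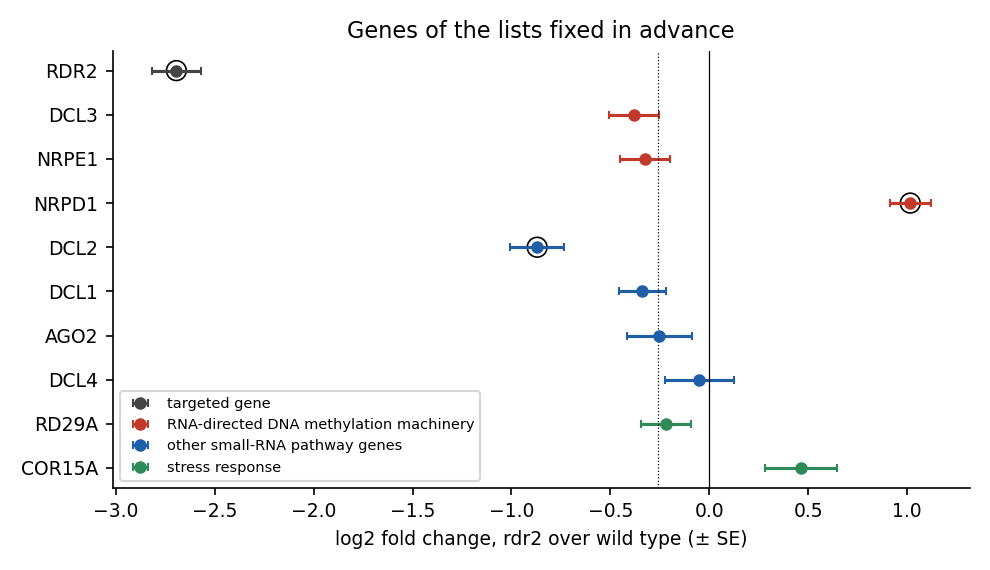
Log2 fold change of the best probe of each fixed-list gene on the array, mutant against wild type, with bars of 1 standard error (n = 3 arrays per group); circled points passed adjusted p 0.05, colours mark the lists, and the dotted line is the median tested probe. RDR2 at -2.69 and DCL2 at -0.87 lie on the falling side and NRPD1 at 1.02 on the rising side.

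Along the chromosomes, lincRNAs with known starts were compared between the regions within 3 Mb of the set centres, where transposons and DNA methylation are dense, and the arms. Among probes with known starts, rises were more and falls less frequent near the centres, and both differences depended on the settings. When known starts were left out in turn, interpolation missed them by 4.53 kb at the median and 21.4 kb at the 95th percentile. With interpolated positions added for the other tested lincRNA probes, 8.13% fell near the centres and 7.66% on the arms, so the deficit of falls did not hold there. Of 94 pericentromeric probes with known starts 11 rose (11.7%), against 10 of 252 on the arms (3.97%, odds ratio 3.21, Fisher's exact p = 0.0112). Of the same probes 4 fell (4.26%) near the centres and 33 (13.1%) on the arms (odds ratio 0.295, exact p = 0.0182). The excess of rises did not hold with normexp (odds ratio 2.38, exact p = 0.0791), with the filter on all 6 arrays (1.67, exact p = 0.408), by the mean of the probes of a name (3.99, exact p = 0.135), by transcript (odds ratio 2.32, exact p = 0.200) nor within 2 Mb (0.736, exact p = 0.777) or 5 Mb (1.76, exact p = 0.258). With interpolated positions it was 1.82 by probe (exact p = 0.00366) but 1.45 by transcript (7.51% against 5.30%, exact p = 0.144), and with array weights 1.93 (exact p = 0.0416). It was larger with the unmoderated test (5.43, exact p = 0.00100), a 2-fold minimum (5.23, exact p = 0.00334), the 75th percentile over all probes (6.58, exact p = 0.000134) and an adjusted p of 0.01 (17.1, exact p = 0.00194). The deficit of falls passed by transcript (0.266, exact p = 0.0270) and within 2 Mb (0.111, exact p = 0.00611) but not within 5 Mb (0.579, exact p = 0.162) or with interpolated positions (1.07, exact p = 0.771; by transcript 0.841, exact p = 0.515). It missed the threshold with quantile normalization and in the deposited table (0.526, exact p = 0.5245 in both), with median scaling (0.888, exact p = 1) and with the filter on all 6 arrays (0.259, exact p = 0.0651). It also missed with array weights (0.667, exact p = 0.116), a 2-fold minimum (0.363, exact p = 0.151), an adjusted p of 0.01 (0.441, exact p = 0.679) and the mean of the probes of a name (0.250, exact p = 0.0724). Trend and robust variance gave 0.161 (exact p = 0.00324) and the unmoderated test 0.149 (exact p = 0.0314). With slide as a random block its odds ratio was 1.34 (exact p = 1). Without mutant replicate 3 the odds ratio of rises was 1.83 (exact p = 0.113). Its value was 10.1 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 1 and 6.68 without mutant replicate 2. The odds ratio of falls missed the threshold without each array in turn, from 0.260 without mutant replicate 2 to 0.632 without wild-type replicate 3.

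**Figure D4:**
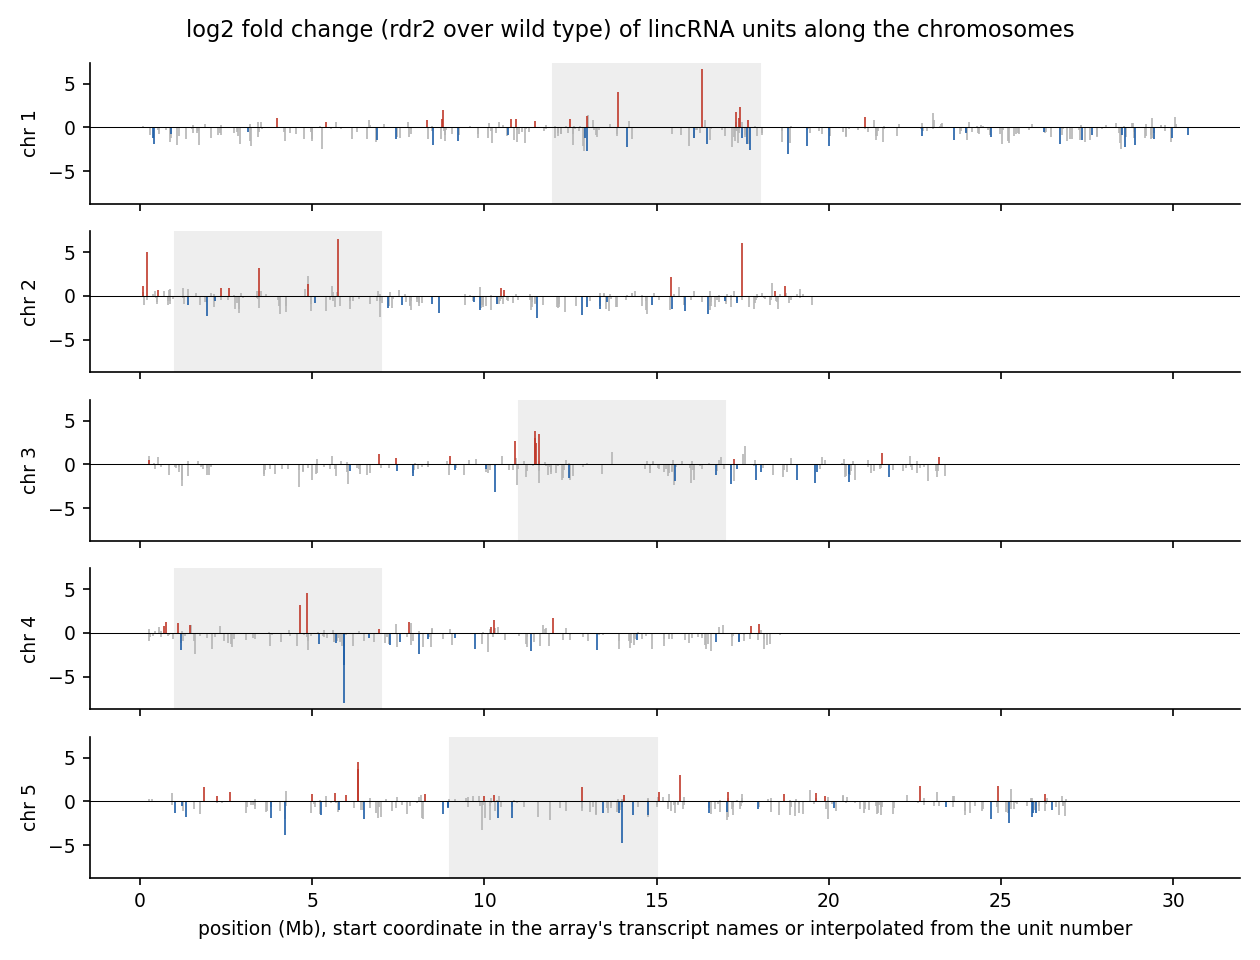
Log2 fold change of each tested lincRNA unit (vertical lines) by position in Mb along chromosomes 1 to 5, with units of unknown start interpolated; red lines are higher and blue lines lower past adjusted p 0.05, grey lines are not called, and the grey band marks 3 Mb on either side of the set centre. Calls of both directions, 78 transcripts higher and 121 lower, are found on every chromosome.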

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

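The alternatives that averaged the arrays of a shared slide, left out the 2 dimmest arrays (mutant replicates 1 and 2), or combined the filter on all 6 arrays with quantile normalization, and those on interpolated positions and on transcripts in place of probes, were chosen after seeing the data. The fall of RDR2 kept its direction and its side of the threshold under all 25 alternatives run for it, with log2 fold changes from -2.95 to -1.99. The named transcripts gave 670 values over the alternatives, of which 597 kept both, 64 kept the direction and lost the call, 3 gained a call and 6 changed direction, all of them for RD29A. Counts of calls moved with nearly every choice, and 17.56% to 37.9% of probes above background per array limit what could be tested. An alternative on the overlap with transposable elements, those on both strands of a locus, and the scan date as a block were not run. Odds ratios of position are left out where the called probes of a direction lay all on one side: for rises with no filter, the filter on at least 1 array, the slide block, averaged slides and the 2 dimmest arrays out, and for falls with these except the slide block, and with the 75th percentile over all probes, normexp and the replicate block. Except where fewer probes, fewer arrays or a stricter threshold give the cause by construction, the cause was not tested.

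In the values that follow, counts are higher or lower probes, lists are means of log2 fold changes, and odds ratios refer to pericentromeric probes. Quantile normalization gave 146 lower over all classes, 68 lower lincRNA, 78 lower other probes, -0.41 for the other small-RNA genes (adjusted p = 0.00641), an odds ratio of falls of 0.526 and 0.25 for RD29A. Median scaling gave 143 lower over all classes, 40 lower other probes, an odds ratio of falls of 0.888 and 0.0076 for RD29A. The 75th percentile over all probes gave 36 lower over all classes, 27 lower lincRNA, 33 higher and 9 lower other probes, 0.28 for the other small-RNA genes and 0.39 for RD29A. Normexp gave 67 lower lincRNA, -0.33 for the other small-RNA genes (adjusted p = 0.00423), an odds ratio of rises of 2.38 and 0.081 for RD29A. The deposited table gave 138 lower over all classes, 68 lower lincRNA, 70 lower other probes, -0.40 for the other small-RNA genes (adjusted p = 0.00811), an odds ratio of falls of 0.526 and 0.25 for RD29A.

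With no filter the counts were 39 higher and 20 lower over all classes, 28 and 10 for lincRNA and 11 and 10 for other probes, and the other small-RNA genes stood at -0.34 (adjusted p = 0.00416). The filter on at least 1 array gave 45 and 34, 29 and 15, and 16 and 19, and 0.27 for RNA-directed DNA methylation (adjusted p = 0.0179). These list values rest on 3 and 4 genes at the preset correlation of camera; with an estimated one, run on the main values alone, adjusted p was 0.484 for RNA-directed DNA methylation and 0.585 for the other small-RNA genes. The filter on all 6 arrays gave 94 lower lincRNA and odds ratios of 1.67 for rises and 0.259 for falls, and with quantile normalization 177 lower over all classes, 48 lower lincRNA, -0.41 for the other small-RNA genes (adjusted p = 0.00230), odds ratios of 1.39 and 0.339, and 0.25 for RD29A. Trend and robust variance gave 214 lower other probes, and the unmoderated test 101 lower lincRNA. Array weights gave 479 and 1499 over all classes, 324 and 934 for lincRNA, 155 and 565 for other probes and an odds ratio of falls of 0.667. The mean of the probes of a name gave 70 and 115, 49 and 74, and 21 and 41, with odds ratios of 3.99 and 0.250. An adjusted p of 0.01 gave 71 and 78, 44 and 39, and 27 and 39, with 0.441 for falls. A 2-fold minimum gave 102 and 161 over all classes, 69 higher lincRNA, 33 and 54 other probes, and 0.363 for falls.

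The replicate block gave 58 higher and 71 lower over all classes, 35 and 43 for lincRNA and 23 and 28 for other probes. The labels number the replicates without pairing them, and deviations from the group means of arrays with the same number correlated at -0.0705, 0.0164 and -0.0235 across 2369 probes, so the fit without the block was kept as the main one; 123 calls were shared with it. With the block NRPD1 (adjusted p = 0.0525; up to 0.223 over its alternatives) and DCL2 (0.0918) missed the threshold, and the odds ratio of rises was 10.06.

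Slide as a random block gave 57 and 55, 33 and 29, and 24 and 26, with an odds ratio of falls of 1.34. Averaging the arrays of a shared slide gave 29 and 16, 19 and 8, and 10 and 8. Without the 2 dimmest arrays, where the lone mutant array is assumed to vary like the wild type, the counts were 26 and 37, 12 and 22, and 14 and 15. Leaving out each array in turn gave 77 to 277 higher and 75 to 770 lower over all classes, 49 to 201 and 38 to 591 for lincRNA, 28 to 76 and 37 to 224 for other probes, and odds ratios of 1.83 to 10.1 for rises and 0.260 to 0.632 for falls. Within 2 Mb of the centre the odds ratio of rises was 0.736, and within 5 Mb 1.76 and 0.579 for falls; interpolated positions gave 1.07 for falls, and transcripts 2.32 for rises.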

Other observations

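The lists and the tests in this part were chosen after the values were seen, except the tests of units next to each other, which were set beforehand. Several jasmonate repressors and seed genes on the array fell in the mutant. Of 4 genes of JAZ repressors, which hold jasmonate responses in check and are themselves induced by jasmonate, 3 fell and none rose: JAZ5 by 1.83 on the log2 scale (SE 0.110, 3.56-fold, adjusted p = 0.000441, n = 3 per group), JAZ6 by 1.16 (adjusted p = 0.0139) and JAZ10 by 0.65 (adjusted p = 0.0191), while TIFY7 stood at -0.48 (adjusted p = 0.0611). All 12 JAZ probes, of 4 genes, lay below the median probe, and 11 did with normexp. Camera gave adjusted p = 2.35e-05 at the preset correlation, which counts probes of 1 gene as nearly independent. With the estimated correlation of 0.46 camera gave adjusted p = 0.520. With the 75th percentile over all probes 10 lay below 0, and JAZ5, JAZ6 and JAZ10 lost their calls (adjusted p = 0.235, 0.669 and 0.978). JAZ6 also lost its call with median scaling (0.0646), and JAZ10 with median scaling (0.291) and the deposited values (0.0505). Of 4 seed maturation genes tested, FUS3, a master regulator of seed filling, fell by 1.79 (SE 0.126, 3.46-fold, adjusted p = 0.000938) and EM1, a late embryogenesis protein, by 0.64 (adjusted p = 0.0246), and LEC1 and ABI3 did not pass (camera adjusted p = 0.0255; adjusted p = 0.520 with an estimated correlation). FUS3 lost its call with the 75th percentile over all probes (-1.18, adjusted p = 0.260), and EM1 lost its call under all 5 other scalings. PAD3, an enzyme of camalexin synthesis, was lower by a log2 fold change of -0.69 (adjusted p = 0.0269). PAD3 lost its call with quantile normalization (0.0695), median scaling (0.289), the 75th percentile over all probes (0.953) and the deposited values (0.0791).

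Precursors of miR156 and miR157, which keep plants juvenile by repressing SPL transcription factors, lay on the lower side together. Of 11 precursors tested, 4 fell (MIR156a, MIR156d, MIR157a and MIR157d) and none rose. All 12 probes lay below the median probe, by 0.78 on average on the log2 scale (mean -1.04). Several were near background in the mutant: MIR156b was well above it on 0 mutant arrays, and MIR156g, MIR157a, MIR157b and 1 probe of MIR157d on 1 each. The dimmest 1115 tested probes had a median of -0.66, so the distance to the median of all probes may overstate the shift of dim ones. Camera gave p = 0.00284, but p = 0.345 with an estimated correlation. MIR156a and MIR157d lost their calls under all 5 other scalings (adjusted p = 0.0783 and 0.0687 with quantile normalization), MIR157a with normexp (0.0567) and the 75th percentile over all probes (0.131), and MIR156d with the latter (0.609). Both with quantile normalization and with the deposited values, 10 of the 12 probes lay below 0, and with normexp the mean was -0.13. None of 8 circadian clock genes passed in limma, and 4 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.222, and adjusted p = 0.587 with an estimated correlation). Of 11 light signalling genes HFR1 fell by 0.72 (adjusted p = 0.0348), and of 11 abscisic acid and cold genes KIN1 rose and COR15B fell. HFR1 lost its call with median scaling (0.288) and the 75th percentile over all probes (0.926), COR15B with these (0.237 and 0.982) and the deposited values (0.0510), and KIN1 with the 75th percentile over all probes (0.107). For these last lists camera gave adjusted p = 0.222 each, and adjusted p = 0.520 and 0.527 with an estimated correlation.

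The split of the 6 arrays by genotype gave 455 calls and the highest other split 2, so no other split gave as many. With 10 splits, the real one included, a share under 0.05 cannot be reached. Each other split mixed the genotypes within its groups, which widens the spread within a group. No slide held both genotypes, so the split cannot tell genotype from slide.

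More probes fell than rose, while the mutant arrays were dimmer and slides were nested in the groups. Falls made up 54.6% of the calls (95% interval 47.3 to 61.7) among the brightest 1115 of the tested probes and 71.6% (63.2 to 79.1) among the dimmest 1115. The median log2 fold change was -0.66 among dim, -0.24 among middle and -0.08 among bright probes, so the shift to lower values was largest in dim signal. With quantile normalization, falls went from 96 to 35 among dim and from 107 to 81 among bright probes, and their shares were 44.3% and 50%. Brightness followed genotype only in part: 24.1% of probes were well above background in wild-type replicate 3 and 24.8% in mutant replicate 3. The excess of falls was lost without wild-type replicate 1 (89 higher and 83 lower) or 2 (77 and 75). Without wild-type replicate 3 the counts were 186 and 770. The excess thus depended on wild-type replicates 1 and 2, which also shared a slide. No fit matched the groups in brightness, so dimmer mutant arrays and a wider fall of transcripts in the mutant were not told apart.

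AT2G01008 and AT3G41761, each near ribosomal RNA genes, rose together. The smallest gap between the lowest mutant and highest wild-type array was 3.65 on the log2 scale, above the widest range within a group, 1.40. Both loci were named by a rule that takes the largest changes with no overlap between the groups' arrays, and slides were nested in the groups. The gap therefore cannot decide on noise shared by the arrays of a slide. The mean log2 fold changes of AT2G01008 and AT3G41761 differed by -0.085, which is what probes of 1 repeated sequence could give. No probe sequence was used here, so a single repeated source cannot be told apart from a rise of both loci. A loss of silencing next to ribosomal DNA in the mutant stays open as an untested biological explanation.

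WRKY40, JAZ5 and FUS3 fell on all of their probes. No clock gene moved 2-fold, a bound set after the values were seen. On the main values the largest shift of a clock gene relative to the median probe was 0.39 on the log2 scale (LHY, 8 genes). CCA1 lay at 0.30 and PRR7 and PRR3 at -0.16 and -0.14. With quantile normalization (median probe -0.02), PRR7 stood at -0.52 and LHY at 0.35 over their probes. There 18 of 24 clock probes lay below the median probe, against 12 on the main values. These values argue only against a harvest at an hour that moves clock genes 2-fold, and smaller differences in hour are not excluded. Less wounding or touch of the mutant plants at harvest might lower WRKY40 and JAZ5, and the highest of the 3 other JAZ genes lay at -0.36 relative to the median probe, but the list was chosen on these data. Less developing seed might lower FUS3; the highest of the 3 other seed genes, LEC1, lay at 0.20 relative to the median probe, and genes of other seed stages need not move with FUS3, so this stays open. An effect of RDR2 loss on these genes is likewise untested.

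Whether lincRNA units next to each other in the order of tested units change together was examined by permuting the calls within chromosomes 10000 times over 1327 units. Untested units can lie between the members of a pair, so the pairs need not be neighbours on the chromosome. Adjacent pairs numbered 7 for rises (permuted mean 4.43, p = 0.149) and 12 for falls (permuted mean 10.66, p = 0.373) in this permutation test. Both counts lay above the permuted mean, so a small excess could not be excluded by the bound set beforehand. AT4TU019690, with the largest fall, and RDR2 lie on the same chromosome; linkage to the mutation was not tested.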
